A study of Homo sapiens with 12 samples.

How the data were processed

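RNA was sequenced from 12 libraries of the cell lines 293T and MCF-7, 3 control and 3 treated with 2-ME in each, all labelled day 1. Per the labels' protocols, total RNA was isolated with Trizol, mRNA was purified with poly-T beads, and the libraries were sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, the tools were fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1, DESeq 1.38.3 and StringTie 2.2.1, named without their roles or order. Whether counting used the strand, and the genome build and annotation, are not given in the sources used here. Overlapping and antisense genes, and near-identical copies such as the tubulins, HSPA1A and HSPA1B, the actins, the histones, the metallothioneins and RPS17, are therefore uncertain.

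The authors deposited 1 table per cell line, each with 20035 genes. Each table was assigned to its line because the sample labels name it, and the column codes ct and tr were read as control and treated, with the replicate number of the label. The columns of the MCF-7 table also carry a code number that the labels do not explain, so all MCF-7 values rest on this reading. The read counts that the authors deposited are whole numbers per gene and library, without normalization per the file headers and values. The FPKM that the authors deposited are the count per kilobase of gene length and scaled to the counted reads of the library, per the file headers and a check of the values. The gene length in the Length column is given in bases as the authors deposited it. Counts were used for all tests, gene length for the check of length bias, and FPKM for that check of the columns alone. Coordinates are as the files give them. Of 19851 genes also in GENCODE 29, 19808 overlap their position there on GRCh38, which was used for GC content and for no printed coordinate. Gene symbols came from the files, and 629 genes had none.

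Each line was fitted alone in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, and a two-sided quasi-likelihood F test of 2-ME against control with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. TMM factors ranged from 0.922 to 1.04 in 293T cells and from 0.955 to 1.04 in MCF-7 cells, and the biological coefficient of variation was 7.01% and 3.57%. The interaction was tested over all 12 libraries in 4 groups. Levels are CPM scaled by TMM. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p under 0.1, so single genes were tested with edgeR. A fold against a group without counts is given as a lower bound, against a floor of 3 counts per library. Groups of the same direction in both lines were compared with one-sided Fisher's exact tests.

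Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were tubulins, mitosis, DNA replication, histones, p53 targets, the amino-acid and integrated stress response, ER chaperones, NRF2 targets, heat shock, hypoxia (HIF-1) targets, glycolysis, cholesterol synthesis, estrogen-responsive genes, NR4A1 targets, NF-kB inflammatory genes, interferon-stimulated genes, immediate early genes, SRF and YAP targets, AhR targets, estrogen metabolism, glucocorticoid-responsive genes, intrinsic apoptosis, autophagy and lysosome, metallothioneins, ribosomal proteins, mitochondrially encoded genes, nuclear OXPHOS, and markers of epithelial, mesenchymal, MCF-7, 293T, fibroblast and blood cells. They hold 658 distinct genes, of which 655 were matched by symbol and 2 by gene identifier, and 1 was not used here. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) and Benjamini-Hochberg adjustment over the lists of a comparison, with camera's estimated correlation and fry beside it. The p of fry tests whether the genes of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares the list with other genes.

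The rule for named genes took, per line, the 6 largest rises and the 6 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and every 2-ME library on one side of every control library. It took the 3 members with the smallest p from each list that passed camera and the 1 with the smallest p from each other list, if its adjusted p was under 0.05. It took, whatever their values, NR4A1, NR4A2, NR4A3, POMC, COMT, CYP1A1, CYP1B1, TUBB and TUBA1B. For the interaction it took the 5 largest differences in each direction by the same filters on symbol, adjusted p and level. The level could be reached in either line, and no separation of 2-ME from control libraries was required. Members of a passing list that moved against it, and genes changed at least 2-fold in both lines, were named after their values were seen.

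The procedure was tested on simulated data with the control means, library sizes and dispersions of these libraries. For 293T cells (13202 genes), it recovered 75 of 100 genes changed 1.5-fold and 87 of 100 changed 2-fold, and called 16 of 13004 unchanged genes, 8.99% of all calls. For MCF-7 cells (12140 genes) these were 75 of 100, 89 of 100 and 13 of 11944 (7.34%). In each line, camera recovered 5 of 5 lists raised 1.4-fold and called 0 of 20 unchanged ones. Genes were simulated independently of each other, so this does not test camera on lists of correlated genes. In the real 293T libraries the estimated correlation within a list was 0.352 for tubulins and 0.919 for mitochondrially encoded genes. For the interaction (11606 genes), 144 of 174 genes with a 2-fold difference were recovered (82.8%). Of 272 calls, 19 were among 11250 genes with equal responses (6.99%), and 109 among 182 genes with a difference of another size. The shares of false calls, 8.99%, 7.34% and 6.99%, all lay above the threshold set for the adjusted p. The simulation changed only 100 genes 1.5-fold and 100 genes 2-fold per line. In the real libraries 52.7% of tested genes changed in 293T and 57.9% in MCF-7 cells. Recovery and false calls were not tested at such shares of changed genes, so these rates may not carry over.

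The alternatives were edgeR's RLE size factors in place of TMM, no filter on low counts, DESeq2 1.42.0 in place of edgeR, the replicate number as a block, 1 fit over all 12 libraries, camera with an estimated correlation, fry, and leaving out each library in turn. For the lists' interaction, which was added after seeing the data, the same alternatives were chosen after seeing the data. Alternatives for normalized values, a pseudocount and a filter on low values, were not run because counts were tested. KEGG pathways in the files' own annotation column, of at least 15 tested genes, were tested with camera after seeing the data. FPKM were left out of all tests, and genes without a count in any library of a fit were left out of it.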

Results

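The series held RNA sequencing of 12 libraries from 2 established human cell lines, with 3 control libraries and 3 libraries of cells given 2-methoxyestradiol in each line. The compound, called 2-ME here, is a metabolite of estradiol that binds tubulin and hinders microtubule assembly. HEK293T (293T) is a transformed embryonic kidney line, and MCF-7 is an estrogen receptor-positive breast cancer line. The submitters' design text gives the purpose: to learn how 2-ME affects gene transcription in both lines, with regard to the activity of the transcription factor Nur77, the orphan nuclear receptor encoded by NR4A1. The labels give day 1 for all 12 libraries and no dose. They write the treated groups as sh2-ME, a prefix they do not explain, and those groups were read as the 2-ME groups of the design text. The MCF-7 columns carry a further code that the labels do not explain, and were read as the MCF-7 libraries because the labels name that table. Marker genes go with this reading. Of 12 fixed MCF-7 line markers, 12 passed the low-count filter in that table and 8 in the 293T table. Of 5 fixed 293T line markers, 0 and 5 did. Total counts per library in 293T cells ranged from 16377867 to 20159920 for control and from 15971042 to 19046639 for 2-ME. In MCF-7 cells they ranged from 13812569 to 16742635 for control and from 12435429 to 14932685 for 2-ME. At these depths 3 counts, taken as the floor in a single library, correspond to 0.149 to 0.241 CPM, counts scaled to the size of the library. Floors, and intervals of a ratio of counts, cover counting error only. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

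The comparison in 293T cells asked which genes 2-ME changes in a line of kidney origin. Of 11 tubulin mRNAs, 9 fell and 0 rose (camera adjusted p = 7.54e-08; adjusted p = 0.258 with an estimated correlation). TUBB, which encodes the main beta-tubulin of most cells (ENSG00000196230, chromosome 6, 30717435 to 30725538), went from 989.9 ± 49.3 CPM in control to 381 ± 14.1 CPM after 2-ME (mean ± SD, n = 3 per group; log2 fold change −1.377, SE 0.0595, edgeR adjusted p = 2.92e-07). EGR1, a transcription factor induced within minutes of growth factor signalling (ENSG00000120738, chromosome 5, 138465479 to 138469303), rose 19.6-fold, from 3.27 ± 0.230 to 64.5 ± 8.38 CPM (n = 3 per group, log2 fold change 4.29, SE 0.124, edgeR adjusted p = 2.59e-08). HSPA8, a cytosolic chaperone of the HSP70 family (ENSG00000109971, chromosome 11, 123057489 to 123063230), rose from 1122 ± 22.966 to 3296 ± 320.1 CPM (1.55, SE 0.0773, n = 3 per group). DDIT4, an inhibitor of mTORC1 signalling, fell from 197 ± 10.2 to 39.4 ± 5.03 CPM (−2.32, SE 0.0867, n = 3 per group).

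Of 13343 genes tested in 293T cells, 7029 changed (52.7%; edgeR quasi-likelihood test, adjusted p under 0.05), 3514 up and 3515 down, with a median absolute log2 fold change of 0.45 among them. A change of at least 2-fold was found for 797 genes, of which 173 rose and 624 fell. The 2 groups did not overlap for 8184 genes (61.3%), where chance gives 10%. Among genes at 1 CPM or more in the higher group, the largest rises were in MMP10, a secreted protease, at least 8.54-fold higher than a control without counts, and in SPRY4 (log2 fold change 5.63, SE 0.469), ETV5 (4.68, SE 0.108), EGR1 (4.29, SE 0.124), CPA4 (3.93, SE 0.315) and ARC (3.80, SE 0.294). SPRY4 encodes a feedback inhibitor of receptor tyrosine kinase signalling, ETV5 an ETS-family transcription factor and ARC a regulator of synapses. The largest falls were in CEACAM1 (log2 fold change −3.71, SE 0.608), CHAC1 (−3.07, SE 0.172), KIF12 (−2.84, SE 0.518), STUM (−2.46, SE 0.163), ATOH1 (−2.46, SE 0.466) and GJD3 (−2.39, SE 0.432). CEACAM1 encodes an adhesion protein, CHAC1 an enzyme that breaks down glutathione, KIF12 a kinesin and ATOH1 a neurogenic transcription factor. SPRY4 in control (5 counts over 3 libraries) and CEACAM1 (5) and KIF12 (7) after 2-ME averaged below the floor, so the sizes of these changes are uncertain.

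Of the 33 gene lists fixed before the data were examined, 8 passed in 293T cells, and camera with an estimated correlation called 0 of these 8. Every other split of these libraries into 3 and 3 also called lists by camera, 4 to 7 of them. The tubulins, which form microtubules, were among them with a median log2 fold change of −0.93. Besides TUBB, the falls included TUBA1A (−1.19, SE 0.0616), TUBB2B (−1.27, SE 0.0852) and TUBA1B (−1.05, SE 0.174). Reads of TUBA1A, TUBA1B and TUBA1C, and of TUBB2A and TUBB2B, may be shared in part, which was not measured here, so the split between these copies is uncertain. Of 21 SRF and YAP targets, genes of the actin cytoskeleton and of adhesion, 13 rose and 0 fell (camera adjusted p = 3.15e-10; adjusted p = 0.104 with an estimated correlation). Among them were CCN2 (log2 fold change 2.33, SE 0.115), CCN1 (2.24, SE 0.0843) and VCL (0.78, SE 0.0502), where CCN1 and CCN2 encode matricellular proteins and VCL vinculin. Of 25 immediate early genes, 17 rose and 3 fell (camera adjusted p = 5.68e-08; adjusted p = 0.151 with an estimated correlation). The leading ones were EGR1 (log2 fold change 4.29, SE 0.124), FOSL1 (3.19, SE 0.126) and FOSL2 (1.91, SE 0.114). FOSL1 and FOSL2 encode AP-1 transcription factors, and the 3 that fell were MYC (−0.98, SE 0.106), KLF6 (−0.79, SE 0.0531) and JUND (−0.58, SE 0.116). Of 13 heat shock genes, 11 rose and 1, HSPB1, fell (−0.58) (camera adjusted p = 2.77e-09; adjusted p = 0.0753 with an estimated correlation). The rise included HSPA8 (log2 fold change 1.55, SE 0.0773), BAG3 (0.92, SE 0.0577) and HSPH1 (0.85, SE 0.0624). Of 35 mitosis genes, 23 rose and 4 fell (camera adjusted p = 7.19e-05; adjusted p = 0.307 with an estimated correlation). The rise included CCNB1 (log2 fold change 0.74, SE 0.0496), ECT2 (0.71, SE 0.0571) and BUB1 (0.56, SE 0.0464), which encode cyclin B1, a regulator of cytokinesis and a spindle checkpoint kinase. The 4 that fell were TOP2A (−0.79, SE 0.0822), PRC1 (−0.78, SE 0.233), UBE2C (−0.65, SE 0.0749) and CDK1 (−0.63, SE 0.0614), which encode a DNA topoisomerase, a microtubule bundler, a ubiquitin-conjugating enzyme and the kinase that drives entry into mitosis. Of 17 ER chaperones, 9 rose and 1, HERPUD1, fell (−0.55) (camera adjusted p = 0.0289; adjusted p = 0.307 with an estimated correlation). Examples were MANF (log2 fold change 0.61, SE 0.0647), HSPA5 (0.54, SE 0.0711) and DNAJC3 (0.53, SE 0.0562).

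In the other direction, 15 of 23 genes of the amino-acid and integrated stress response fell and 4 rose (camera adjusted p = 3.55e-08; adjusted p = 0.104 with an estimated correlation). The fall included CHAC1 (log2 fold change −3.07, SE 0.172), DDIT4 (−2.32, SE 0.0867) and VLDLR (−1.48, SE 0.103), where VLDLR encodes a lipoprotein receptor. The 4 that rose were ATF5 (1.16, SE 0.130), ATF3 (0.42, SE 0.0710), PPP1R15A (0.70, SE 0.0752) and SLC7A5 (0.51, SE 0.0689). ATF5 and ATF3 encode transcription factors, PPP1R15A a regulator of the phosphatase of eIF2 alpha and SLC7A5 an amino-acid transporter. Of 30 DNA replication genes, 19 fell, among them MCM5 (log2 fold change −1.08, SE 0.0488), CDC45 (−0.85, SE 0.0692) and MCM2 (−0.78, SE 0.0640), all parts of the replicative helicase, and 1, RRM2, rose (0.16; camera adjusted p = 1.89e-06; adjusted p = 0.258 with an estimated correlation). Genes named here as the members that moved against their list were chosen after their values were seen.

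NR4A1 itself (ENSG00000123358, chromosome 12, 52022832 to 52059507) stood at 10.7 ± 0.931 CPM in control and 11.1 ± 2.75 CPM after 2-ME in 293T cells (n = 3 per group; log2 fold change 0.057, SE 0.167, edgeR adjusted p = 0.796). Its relatives did not pass either, with 0.0049 for NR4A2 (SE 0.188, edgeR adjusted p = 0.984) and 0.35 for NR4A3 (SE 0.135, edgeR adjusted p = 0.0518). NR4A3 passed with other library scaling (0.0460) and in a fit of all 12 libraries (0.0326). Of 14 tested NR4A1 targets, 3 rose and 7 fell, with a median of −0.28, and the list did not pass (camera adjusted p = 0.0892). The member with the smallest p was UCP2, a mitochondrial carrier, which fell (−1.28, SE 0.0820). POMC, a known NR4A1 target, was at 0.773 and 0.623 CPM (edgeR adjusted p = 0.506). Of the genes of estrogen metabolism named whatever their values, CYP1B1 rose from 6.52 ± 0.586 to 12.985 ± 0.891 CPM (0.999, SE 0.115). CYP1A1 had −0.31 (SE 0.271, edgeR adjusted p = 0.363) and COMT 0.063 (SE 0.106, edgeR adjusted p = 0.645).

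The other lists did not pass in 293T cells. The members that rose and fell, with camera's adjusted p for the list in parentheses, were as follows. Among lists of stress and signalling they were, for p53 targets 10 and 11 of 29 (0.801), NRF2 targets 4 and 4 of 18 (0.841), hypoxia (HIF-1) targets 4 and 11 of 22 (0.189), NF-kB inflammatory 3 and 2 of 12 (0.592), interferon-stimulated 1 and 5 of 15 (0.304) and intrinsic apoptosis 9 and 5 of 22 (0.308). Among lists of hormones and metabolism they were, for estrogen-responsive 4 and 8 of 17 (0.308), AhR targets 2 and 1 of 6 (0.381), estrogen metabolism 4 and 2 of 10 (0.801), glucocorticoid-responsive 5 and 3 of 9 (0.724), glycolysis 1 and 6 of 17 (0.208), cholesterol synthesis 3 and 14 of 23 (0.152) and autophagy and lysosome 4 and 6 of 24 (0.928). Among lists of structural and housekeeping genes they were, for histones 4 and 2 of 14 (0.308), ribosomal proteins 2 and 9 of 73 (0.339) and nuclear OXPHOS 2 and 8 of 36 (0.549), and among cell type markers, for epithelial markers 2 and 5 of 9 (0.726), mesenchymal markers 3 and 5 of 14 (0.304), MCF-7 line markers 1 and 3 of 8 (0.801) and 293T line markers 2 and 1 of 5 (0.726). Too few members were tested of metallothioneins (1 rose and 1 fell of 3), fibroblast markers (4 fell of 4) and blood cell markers (1 fell of 2). By the rule for named genes, members of these lists that rose were H2BC5 (log2 fold change 1.26, SE 0.162), PMAIP1 (0.93, SE 0.0495), NFKB1 (0.75, SE 0.0677), TIPARP (0.73, SE 0.0736) and LIN28B (0.83, SE 0.0556). Those that fell were TSC22D3 (log2 fold change −1.73, SE 0.0694), IFIT1 (−1.49, SE 0.160), CDH1 (−1.49, SE 0.208), WIPI1 (−1.06, SE 0.144), COL1A1 (−1.04, SE 0.149), MT1F (−0.96, SE 0.310), RPS17 (−0.96, SE 0.105), SLC7A11 (−0.95, SE 0.0697), HILPDA (−0.94, SE 0.0966), SNAI2 (−0.83, SE 0.0572), CD19 (−0.69, SE 0.172), PFKL (−0.62, SE 0.0575), INSIG1 (−0.61, SE 0.0472), STC2 (−0.57, SE 0.0556) and ATP5MC1 (−0.27, SE 0.0508). TSC22D3 encodes a leucine zipper protein induced by glucocorticoids. MT1F missed the threshold with DESeq2 (adjusted p = 0.0894) and without 5 of the 6 libraries left out in turn (0.0539 to 0.0686).

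Of 13 mitochondrially encoded genes, 3 rose in 293T cells, 0 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.308). MT-ND1 had 0.54 (SE 0.183, edgeR adjusted p = 0.0299), lost with DESeq2 (0.105) and without any of the 3 controls (0.103, 0.0917 and 0.0706). These genes took 6.33% of the counts in 2-ME replicate 1, against 4.30% and 4.40% in the other 2-ME libraries and 4.49% to 4.81% in the controls. That library also differed most from its own replicates, with a chi-square per degree of freedom of 19.3 and 20.7, where other pairs of replicates had 1.77 to 3.28. Without it, 8235 genes changed, 828 of them at least 2-fold, and 8 lists passed.

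Adjusted over the list alone, the counts of members that rose and fell in 293T cells became 24 and 5 for mitosis, 5 and 15 for the integrated stress response, 10 and 1 for ER chaperones and 18 and 3 for immediate early genes. They became 4 and 14 for cholesterol synthesis, 4 and 4 for NF-kB, 2 and 0 for AhR targets, 4 and 3 for estrogen metabolism, 3 and 3 for autophagy, 0 and 7 for ribosomal proteins, 1 and 2 for nuclear OXPHOS, 2 and 6 for epithelial markers, 2 and 3 for MCF-7 line markers and 1 and 1 for blood cell markers. The other lists kept their counts apart from the mitochondrially encoded genes, given above. Median, mean and test differed in sign for AhR targets (−0.23, 0.061, up), estrogen metabolism (−0.026, −0.036, up), glucocorticoid-responsive genes (0.21, 0.11, down) and intrinsic apoptosis (0.034, −0.029, up), while metallothioneins had a median of 0.17 and a mean of −0.18.

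The comparison in MCF-7 cells asked which genes 2-ME changes in an estrogen receptor-positive line. TOP2A, a topoisomerase of dividing cells (ENSG00000131747, chromosome 17, 40388525 to 40417896), went from 335 ± 3.51 to 75.7 ± 1.10 CPM (n = 3 per group; log2 fold change −2.15, SE 0.0380, edgeR adjusted p = 1.30e-33). Of 34 mitosis genes, 32 fell and 1, CDC20, rose (0.34; camera adjusted p = 3.78e-35; adjusted p = 0.0457 with an estimated correlation). Of 23 interferon-stimulated genes, 22 rose and 0 fell (camera adjusted p = 1.70e-20; adjusted p = 0.0240 with an estimated correlation). IFIT1, an antiviral RNA-binding protein, rose from 165 ± 6.79 to 316 ± 6.32 CPM (0.94, SE 0.0360, n = 3 per group). CYP1A1, which hydroxylates estradiol and is induced through the aryl hydrocarbon receptor (ENSG00000140465, chromosome 15, 74719542 to 74725536), rose from 0.119 ± 0.0925 to 2.64 ± 0.618 CPM (4.43, SE 0.496, edgeR adjusted p = 4.90e-10, n = 3 per group), and its control mean lay below the floor. HMOX1, heme oxygenase and an NRF2 target, rose from 59.3 ± 2.82 to 150 ± 5.18 CPM (1.34, SE 0.0474, n = 3 per group).

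Of 12520 genes tested in MCF-7 cells, 7253 changed (57.9%; edgeR adjusted p under 0.05), 3547 up and 3706 down, with a median absolute log2 fold change of 0.43 among them. A change of at least 2-fold was found for 941 genes, of which 637 rose and 304 fell. The groups did not overlap for 7668 genes (61.2%, against 10% by chance). By the rule for named genes the largest rises were in COLEC12, a scavenger receptor, at least 4.87-fold above a control without counts, and in CXCL1 (log2 fold change 4.90, SE 0.701), CYP1A1 (4.43, SE 0.496), IL16 (4.25, SE 0.415), ST8SIA5 (3.98, SE 0.574) and COL20A1 (3.77, SE 0.433). CXCL1 and IL16 encode cytokines. CXCL1 had 2 counts over the 3 control libraries and 67 after 2-ME, a ratio of 35.1 (95% counting interval 9.35 to 296), and CYP1A1 (5 counts), IL16 (8) and ST8SIA5 (4) also averaged below the floor in control, so the sizes of these changes are uncertain. The largest falls were in NPPB (log2 fold change −2.66, SE 0.497), KIF12 (−2.57, SE 0.228), PADI1 (−2.30, SE 0.148), SLC6A19 (−2.29, SE 0.389), SCN2B (−2.23, SE 0.219) and SPC24 (−2.19, SE 0.188), where NPPB encodes a natriuretic peptide, PADI1 a peptidylarginine deiminase, SLC6A19 an amino-acid transporter and SPC24 a kinetochore protein.

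In MCF-7 cells 18 lists passed, and 4 of them also with an estimated correlation: mitosis, interferon-stimulated genes, glycolysis and NF-kB. Every other split of these libraries into 3 and 3 also called lists by camera at the preset correlation, 3 to 12 of them. The 34 mitosis genes had a median log2 fold change of −1.15. Examples were TOP2A (log2 fold change −2.15, SE 0.0380), CDK1 (−1.83, SE 0.0695) and UBE2C (−1.80, SE 0.0684). The interferon-stimulated genes had a median of 0.73. Examples were IFIT3 (log2 fold change 1.10, SE 0.0440), IFIT2 (1.05, SE 0.0375) and IFIT1 (0.94, SE 0.0360). Of 20 NF-kB inflammatory genes, 14 rose and 1, IER3, fell (−0.24) (camera adjusted p = 7.63e-06; adjusted p = 0.0457 with an estimated correlation). Examples were CXCL8 (log2 fold change 2.11, SE 0.0534), BIRC3 (0.72, SE 0.0325) and NFKB1 (0.57, SE 0.0496). CXCL8 encodes the chemokine interleukin-8 and BIRC3 an inhibitor of cell death. Of 16 glycolysis genes, 12 fell and 2, GPI (0.13) and PKM (0.080), rose (camera adjusted p = 3.04e-06; adjusted p = 0.0457 with an estimated correlation). Examples were HK1 (log2 fold change −0.66, SE 0.0286), ENO2 (−0.64, SE 0.0283) and GAPDH (−0.49, SE 0.0214). HK1 encodes hexokinase, the first enzyme of the pathway.

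Other lists that rose in MCF-7 cells lost their call with an estimated correlation. Of 29 p53 targets, 22 rose and 3 fell (camera adjusted p = 2.31e-09; adjusted p = 0.0541 with an estimated correlation). Examples were ZMAT3 (log2 fold change 1.30, SE 0.0577), AEN (1.15, SE 0.0529) and TP53INP1 (0.97, SE 0.0365). The 3 that fell were PLK3 (−1.21, SE 0.151), SESN2 (−0.35, SE 0.0579) and PHLDA3 (−0.34, SE 0.0614), and CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, had 0.12 (SE 0.0311). Of 19 NRF2 targets, genes of antioxidant defence, 15 rose and 3 fell (camera adjusted p = 1.52e-06; adjusted p = 0.0603 with an estimated correlation). Among them were HMOX1 (log2 fold change 1.34, SE 0.0474), TXNRD1 (1.05, SE 0.0317) and SLC7A11 (0.77, SE 0.0407), and the 3 that fell were OSGIN1 (−0.74, SE 0.0710), FTH1 (−0.24, SE 0.0335) and FTL (−0.20, SE 0.0300), an oxidative stress-induced growth inhibitor and the ferritin chains. Of 17 ER chaperones, 12 rose and 0 fell (camera adjusted p = 9.35e-05; adjusted p = 0.0729 with an estimated correlation). Examples were DNAJB9 (log2 fold change 0.95, SE 0.0483), HSPA5 (0.92, SE 0.0264) and EDEM1 (0.45, SE 0.0379). Of 21 histone genes, 8 rose and 2 fell (camera adjusted p = 0.0468; adjusted p = 0.243 with an estimated correlation). Examples were H1-2 (log2 fold change 0.98, SE 0.0598), H2BC12 (0.92, SE 0.0798) and H2BC5 (0.55, SE 0.0494). The 2 that fell were H2AX (−0.35, SE 0.128) and H3-3B (−0.17, SE 0.0300). The libraries were poly(A)-selected, most histone mRNAs carry no poly(A) tail, and the list missed the threshold with DESeq2 (0.0666), with the replicate number as a block (0.0518) and without control replicate 1 (0.101), 2-ME replicate 1 (0.0560) or 2-ME replicate 3 (0.0591).

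Other lists fell in MCF-7 cells and lost their call with an estimated correlation. Of 24 hypoxia targets, 19 fell and 3 rose, with ANKRD37 (log2 fold change −1.65, SE 0.104), CA12 (−0.81, SE 0.0293) and SLC2A1 (−0.57, SE 0.0305) (camera adjusted p = 8.47e-07; adjusted p = 0.0541 with an estimated correlation). The 3 that rose were KDM3A (0.38, SE 0.0287), P4HA1 (0.28, SE 0.0303) and VEGFA (0.13, SE 0.0270), and SLC2A1 encodes a glucose transporter. Of 21 estrogen-responsive genes, 14 fell and 3 rose (camera adjusted p = 0.000308; adjusted p = 0.0603 with an estimated correlation). Examples were GREB1 (log2 fold change −0.90, SE 0.0305), CA12 (−0.81, SE 0.0293) and TFF1 (−0.51, SE 0.0252). The 3 that rose were PDZK1 (0.80, SE 0.218), NRIP1 (0.59, SE 0.0337) and STC2 (0.44, SE 0.0275). Of 12 MCF-7 line markers, 8 fell and 3, FOXA1 (0.28), EPCAM (0.18) and XBP1 (0.13), rose (camera adjusted p = 0.000773; adjusted p = 0.0603 with an estimated correlation), and of 16 epithelial markers 9 fell and 3, CLDN7 (0.22), EPCAM and GRHL2 (0.13), rose (camera adjusted p = 0.00481; adjusted p = 0.0729 with an estimated correlation). Both lists hold the keratins KRT18 (log2 fold change −0.76, SE 0.0351), KRT8 (−0.50, SE 0.0216) and KRT19 (−0.42, SE 0.0240). Of 21 SRF and YAP targets, 13 fell, with ACTG1 (log2 fold change −0.77, SE 0.0217), FLNA (−0.52, SE 0.0243) and ACTB (−0.45, SE 0.0258), and 3 rose, ACTA2 (1.72, SE 0.396), CCN2 (1.42, SE 0.345) and TAGLN (1.10, SE 0.206) (camera adjusted p = 0.000457; adjusted p = 0.316 with an estimated correlation). ACTB and ACTG1 encode nearly identical actins and may share reads, which was not measured here.

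Of 30 DNA replication genes in MCF-7 cells, 16 fell and 3 rose (camera adjusted p = 0.00563; adjusted p = 0.0729 with an estimated correlation). RRM2 (log2 fold change −1.98, SE 0.0600) and RFC3 (−0.77, SE 0.0682) fell, which encode a subunit of ribonucleotide reductase and of the clamp loader, and PCNA (0.99, SE 0.0951), FEN1 (0.41, SE 0.104) and MCM4 (0.17, SE 0.0670) rose, where PCNA encodes the sliding clamp. Of 73 ribosomal proteins, 45 fell and 4 rose (camera adjusted p = 0.00263; adjusted p = 0.596 with an estimated correlation). Examples were RPL3 (log2 fold change −0.49, SE 0.0241), RPL7A (−0.41, SE 0.0276) and RPL6 (−0.30, SE 0.0252). The 4 that rose were RPL26 (0.98, SE 0.164), RPS17 (0.93, SE 0.140), RPS10 (0.79, SE 0.228) and RPS15A (0.54, SE 0.127). Of 13 mitochondrially encoded genes, 12 fell and 1, MT-CO3, rose (0.15; camera adjusted p = 1.73e-05; adjusted p = 0.327 with an estimated correlation), with MT-ND6 (log2 fold change −0.89, SE 0.0439), MT-ND5 (−0.74, SE 0.0363) and MT-CO2 (−0.68, SE 0.0366). These genes took 3.18% to 3.58% of the counts in control and 2.47% to 2.80% after 2-ME. Of 36 nuclear OXPHOS genes, which encode respiratory chain subunits, 20 fell and 2, SDHA (0.74) and UQCRFS1 (0.33), rose (camera adjusted p = 0.0287; adjusted p = 0.449 with an estimated correlation). Examples were NDUFV1 (log2 fold change −0.78, SE 0.0548), UQCRC2 (−0.48, SE 0.0373) and NDUFS2 (−0.45, SE 0.0502). Of 8 mesenchymal markers, TGFBI (log2 fold change −0.995, SE 0.0298) and FN1 (−0.83, SE 0.0272) fell and SNAI1 (1.381, SE 0.235) and ZEB1 (1.35, SE 0.391) rose. The test of that list pointed down, its median was 0.028 and its mean 0.17, and its call (camera adjusted p = 0.0287; adjusted p = 0.176 with an estimated correlation) was lost without a low-count filter (0.0990).

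NR4A1 rose in MCF-7 cells, from 12.4 ± 1.36 to 16.8 ± 3.21 CPM (n = 3 per group; log2 fold change 0.43, SE 0.122, edgeR adjusted p = 0.00243), with overlapping replicates. In 11 other settings it lay between 0.32 and 0.58 (adjusted p 8.66e-05 to 0.0453). NR4A3 (ENSG00000119508, chromosome 9, 99821855 to 99866891) rose from 11.3 ± 0.430 to 21.8 ± 2.82 CPM (0.94, SE 0.107, edgeR adjusted p = 1.09e-09). NR4A2 had 0.17 (SE 0.0745, edgeR adjusted p = 0.0508), which passed with other scaling (0.0451), with the block (0.0475) and without control replicate 2 (0.0261) or 2-ME replicate 2 (0.00517). Of 12 NR4A1 targets, 3 rose and 3 fell (camera adjusted p = 0.642, median 0.048). The member with the smallest p, IDH1, a cytosolic isocitrate dehydrogenase, rose (0.89, SE 0.0654). POMC lay at or below the floor. Of the genes of estrogen metabolism named whatever their values, CYP1B1 rose from 150.5 ± 5.19 to 255 ± 1.84 CPM (0.76, SE 0.0365), and COMT had 0.026 (SE 0.0997, edgeR adjusted p = 0.841). TUBB fell from 325 ± 1.45 to 206 ± 3.48 CPM (−0.65, SE 0.0331). TUBA1B had −0.35 (SE 0.118, edgeR adjusted p = 0.0105), a call lost without control replicate 2 (0.116) or 3 (0.0618) and in a fit of all 12 libraries (0.131).

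The other lists did not pass in MCF-7 cells. Members that rose and fell, with camera's adjusted p in parentheses, were, for tubulins 2 and 3 of 11 (0.713), heat shock 5 and 4 of 13 (0.702), amino-acid and integrated stress response 7 and 6 of 22 (0.175), immediate early 11 and 7 of 23 (0.521), intrinsic apoptosis 10 and 6 of 23 (0.0728) and autophagy and lysosome 9 and 8 of 24 (0.662). They were, for cholesterol synthesis 9 and 5 of 23 (0.119), estrogen metabolism 5 and 1 of 13 (0.233) and glucocorticoid-responsive 4 and 2 of 8 (0.578). Too few members were tested of AhR targets (3 rose and 1 fell of 4), metallothioneins (1 and 3 of 4), fibroblast markers (0 passed of 2), blood cell markers (0 of 1) and 293T line markers (0 tested). By the rule for named genes, TSC22D3 (log2 fold change 1.75, SE 0.0644), SQSTM1 (0.96, SE 0.0328), CASP7 (0.94, SE 0.0537) and LDLR (0.72, SE 0.0365) rose, which encode a glucocorticoid-induced leucine zipper protein, an autophagy receptor, a caspase and the low-density lipoprotein receptor. MT2A (log2 fold change −1.504, SE 0.0674), EGR1 (−1.26, SE 0.0546) and HSPB1 (−0.94, SE 0.0276) fell, where MT2A encodes a metallothionein and HSPB1 a small heat shock protein. Adjusted over the list alone, the counts of members that rose and fell became 23 and 3 for p53 targets, 8 and 5 for heat shock, 2 and 13 for glycolysis, 9 and 6 for cholesterol synthesis, 4 and 15 for estrogen-responsive genes and 12 and 7 for immediate early genes, while the other lists kept theirs. Heat shock (median 0.16, mean 0.11, test down) and autophagy (−0.060, 0.085, up) also differed in sign.

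In every gene of the rule for named genes that passed in its line, each 2-ME library lay outside the range of the control libraries, except NR4A1 and TUBA1B in MCF-7 cells. The rule required this of the largest rises and falls and took list members by their smallest p, so it is no separate support. Of all tested genes, 61.3% in 293T and 61.2% in MCF-7 cells had groups that did not overlap. Genes of several lists at once, such as SLC7A11, CA12 and STC2, count in each.

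**Figure D1:**
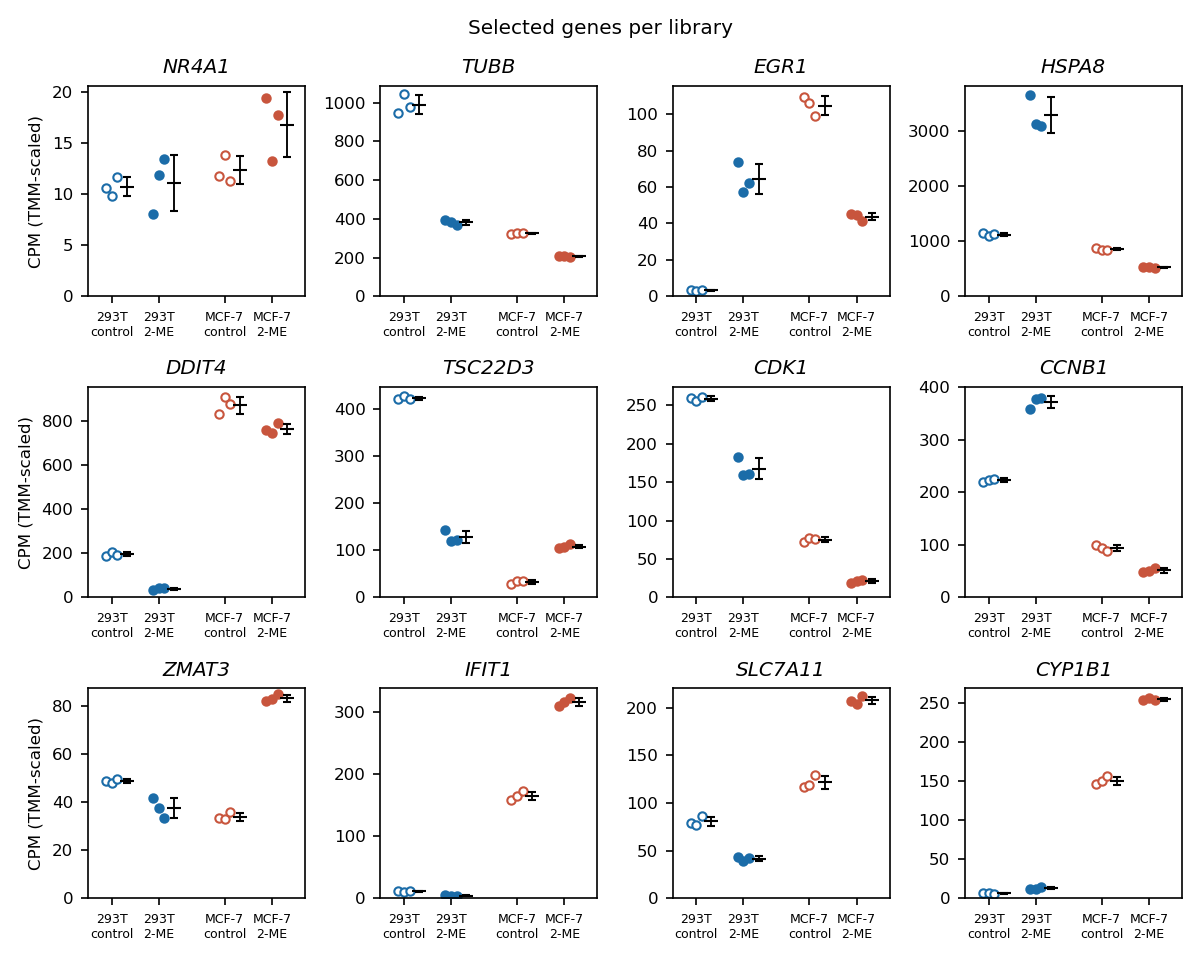
Expression of 12 genes in CPM (vertical axes, from 0) in each library of 293T (blue) and MCF-7 cells (red), with open points for control and filled points for 2-ME; dashes with bars give the mean ± SD of 3 libraries. TUBB fell from 989.9 to 381 CPM in 293T cells, and TSC22D3 fell from 422 to 128 CPM there and rose from 32.2 to 108 CPM in MCF-7 cells.

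Whether the lines responded alike was tested by the interaction of cell line and treatment, over all 12 libraries, and for gene lists this test was added after the data were seen. The mitosis genes differed most by this test: 33 of 34 had a higher response in 293T cells and 0 a lower one, with a median difference in log2 fold change, 293T minus MCF-7, of 1.496 (camera adjusted p = 1.30e-56; adjusted p = 0.000999 with an estimated correlation). EGR1 rose in 293T cells (4.29) and fell in MCF-7 cells (−1.26), a difference of 5.59 (SE 0.134, edgeR adjusted p = 2.41e-17). TSC22D3 fell in 293T cells (−1.73) and rose in MCF-7 cells (1.75), a difference of −3.44 (SE 0.103, edgeR adjusted p = 8.18e-16). HSPA8 rose in 293T cells and had −0.70 in MCF-7 cells, a difference of 2.29 (SE 0.0749, edgeR adjusted p = 3.99e-15). The response of NR4A1 itself did not pass as different (−0.34, SE 0.229, edgeR adjusted p = 0.240), and that of NR4A3 was lower in 293T cells (−0.56, SE 0.181, edgeR adjusted p = 0.0154).

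Of 14270 genes tested, 6201 had a response that differed between the lines (43.5%; edgeR adjusted p under 0.05), higher in 293T cells for 3413 and lower for 2788. Of 11612 genes also tested in each line alone, 5786 differed, of which 1413 were called in opposite directions, 848 in the same direction, 1549 in 293T cells alone, 1847 in MCF-7 cells alone and 129 in neither. A list's response was higher in 293T cells for SRF and YAP targets (16 higher and 3 lower of 22, median 0.93, camera adjusted p = 1.38e-12, and adjusted p = 0.0156 with an estimated correlation), heat shock genes (10 higher and 0 lower of 13, median 0.41, camera adjusted p = 3.38e-08, and adjusted p = 0.00284 with an estimated correlation), immediate early genes (12 higher and 6 lower of 24, median 0.38, camera adjusted p = 8.45e-06, and adjusted p = 0.0530 with an estimated correlation) and mitochondrially encoded genes (11 higher and 0 lower of 13, median 0.81, camera adjusted p = 0.00619, and adjusted p = 0.644 with an estimated correlation). The last 2 did not hold with an estimated correlation. In 293T cells 2-ME replicate 1 had the highest share of mitochondrial counts (6.33%). Without that library 11 lists still differed, and whether it accounts for the difference of the mitochondrially encoded genes is not shown here. A list's response was lower in 293T cells for the integrated stress response (5 higher and 13 lower of 23, median −0.45, camera adjusted p = 3.38e-08, and adjusted p = 0.00756 with an estimated correlation), p53 targets (2 higher and 19 lower of 29, median −0.55, camera adjusted p = 7.75e-08, and adjusted p = 0.00284 with an estimated correlation) and NRF2 targets (1 higher and 11 lower of 19, median −0.29, camera adjusted p = 0.000104, and adjusted p = 0.0156 with an estimated correlation). It was also lower for tubulins (0 higher and 7 lower of 12, median −0.62, camera adjusted p = 0.000632, and adjusted p = 0.190 with an estimated correlation), interferon-stimulated genes (0 higher and 9 lower of 23, median −0.94, camera adjusted p = 0.000827, and adjusted p = 0.0158 with an estimated correlation) and cholesterol synthesis (4 higher and 10 lower of 23, median −0.30, camera adjusted p = 0.00619, and adjusted p = 0.0460 with an estimated correlation). The medians of tubulins and NRF2 targets were −0.58 and −0.33 without the 1 member of each that had a group without counts, and that of interferon-stimulated genes stayed at −0.94 without 4 such members.

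The NR4A1 targets did not pass, with 1 member higher and 7 lower in 293T cells of 16 (camera adjusted p = 0.0656, median −0.62). The other lists did not pass either, with camera's adjusted p in parentheses: DNA replication (0.507), histones (0.884), ER chaperones (0.712), hypoxia (HIF-1) targets (0.507), glycolysis (0.274), estrogen-responsive (0.757), NF-kB inflammatory (0.388), AhR targets (0.818), estrogen metabolism (0.163), glucocorticoid-responsive (0.656), intrinsic apoptosis (0.307), autophagy and lysosome (0.757), ribosomal proteins (0.507), nuclear OXPHOS (0.241), epithelial markers (0.787), mesenchymal markers (0.463), MCF-7 line markers (0.731) and 293T line markers (0.787). Median and test differed in sign for histones (0.18, lower), ER chaperones (0.024, lower), glucocorticoid-responsive genes (0.86, lower), epithelial markers (−0.15, higher) and autophagy (0.078, lower). Among the genes with the largest differences, SPRY4 had 5.56 (SE 0.640, edgeR adjusted p = 4.08e-07). The others with a positive difference, MMP10 (2.18e-06), WT1 (0.00234) and SLC6A19 (0.0258), and those with a negative one, COLEC12 (5.81e-06), OTOG (0.000638), CLEC4F (0.000916), PDE1B (0.00152) and CCDC38 (0.000273), had a group without counts, so their adjusted p is given and no size. In that line the other group often held few counts over its 3 libraries. It held 3 for SLC6A19 in 293T cells, and in MCF-7 cells 7 for WT1, OTOG and CLEC4F, 11 for PDE1B and 25 for CCDC38. These genes were not tested in that line alone. It held 66 for MMP10 in 293T cells and 42 for COLEC12 in MCF-7 cells. Their rank among the largest differences rests on the group without counts. The call for SLC6A19 was lost without 2-ME replicate 3 of 293T cells. CYP1A1 rose in MCF-7 cells and had a difference of −4.73 (SE 0.586, edgeR adjusted p = 1.23e-06).

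Genes changed in the same direction in both lines numbered 2365. Both lines raised 1351 genes, where 952.6 were expected from the counts of 3347 and 3305 (one-sided Fisher's exact test, p = 1.02e-70), and lowered 1014, where 860.4 were expected from 2885 and 3463 (p = 5.51e-13). These are 2 tests on 1 set of genes, and genes are not independent replicates. Opposite calls numbered 1413, of which 799 rose in 293T cells and fell in MCF-7 cells (998 expected) and 614 did the reverse (821 expected). Across these genes the log2 fold changes of the lines had a Pearson r of 0.119 and a Spearman rho of 0.164. Within each line the log2 fold change also tended to fall with GC content (Spearman rho −0.222 in 293T and −0.121 in MCF-7 cells). Whether that trend accounts for part of the overlap was not tested. Changes of at least 2-fold in both lines went the same way for 43 genes and opposite ways for 27. Chosen after their values were seen, ETV5 (4.68 in 293T and 2.63 in MCF-7 cells), PYGM, a glycogen phosphorylase (1.55 and 1.77), and ARC (3.80 and 1.36) rose in both, and KIF12 (−2.84 and −2.57) and ANKRD37 (−1.17 and −1.65) fell in both. IFIT2 (−3.78 and 1.05), WNT5A, a secreted signalling protein (−1.12 and 2.04), and IL11 (1.51 and −1.29) went opposite ways. IFIT2 in 293T cells had 37 counts over the control libraries and 2 after 2-ME, a ratio of 0.0627 (95% counting interval 0.00732 to 0.243).

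**Figure D2:**
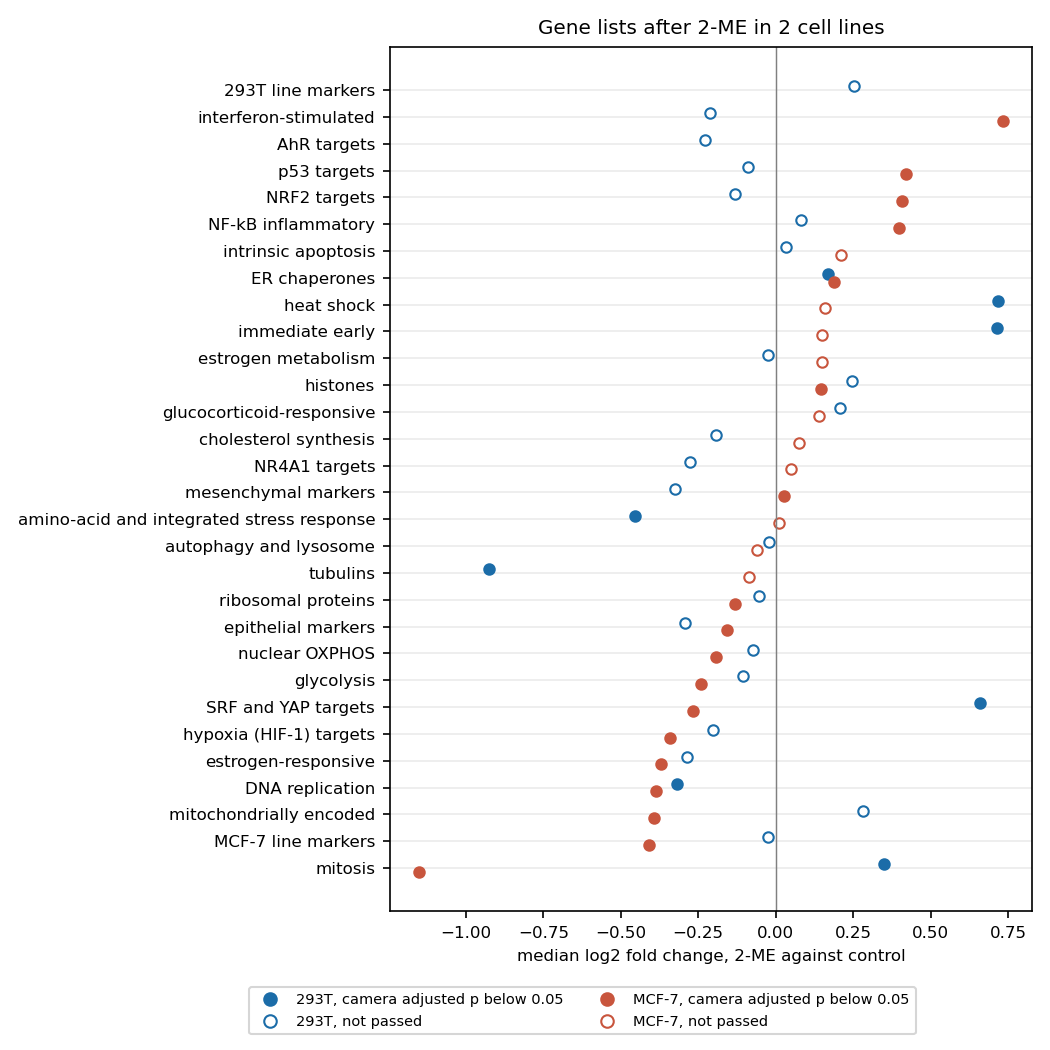
Median log2 fold change after 2-ME (horizontal axis) of each gene list tested in at least 1 line, for 293T (blue) and MCF-7 cells (red), filled where camera's adjusted p was under 0.05. The mitosis list lies at 0.35 in 293T cells and −1.15 in MCF-7 cells, and the tubulins at −0.93 and −0.088.

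**Figure D3:**
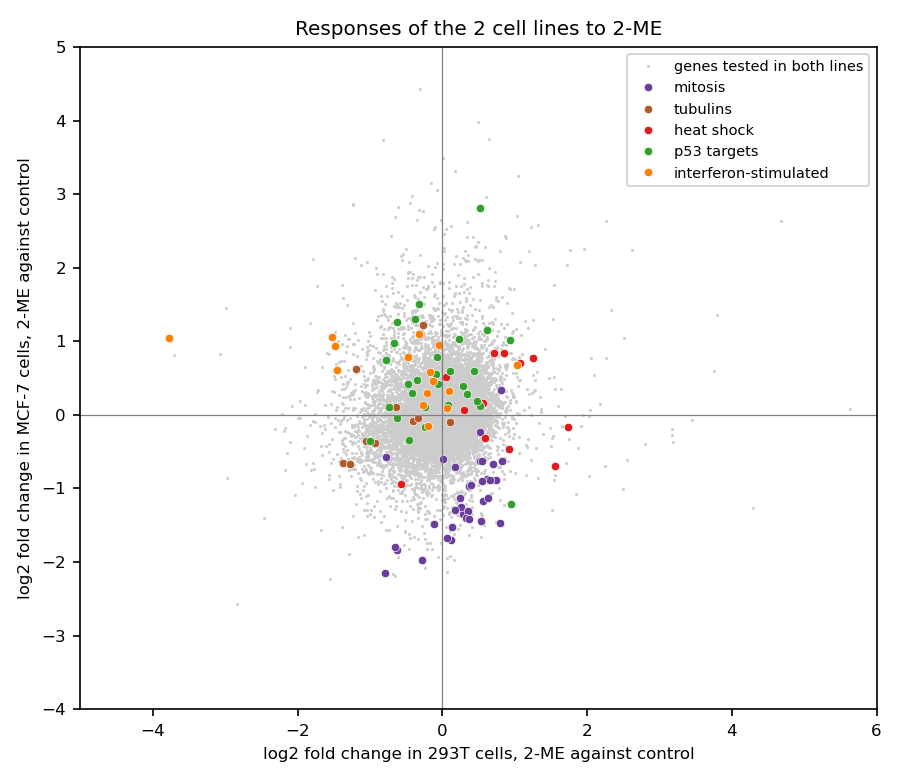
Log2 fold change after 2-ME in 293T cells (horizontal axis) and MCF-7 cells (vertical axis) of each of 11612 genes tested in both (grey), 2 of them outside the axes, with the members of 5 lists in colour. The points spread widely (Spearman rho 0.164 across genes), and 33 of 34 mitosis genes had a higher response in 293T cells by the interaction test.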

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

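Among the tests of this part, those of shared reads and of 2-ME replicate 1 for the tubulins, of library scaling and of 2-ME replicate 1 for mitosis, and of the share of 293T RNA, were chosen only after the result was seen. The lists and genes given with values after the third pattern, and the first 2 patterns, have a response to 2-ME that differs between the cell lines by the interaction test, edgeR for genes and camera for lists, each past an adjusted p of 0.05, and the third pattern was noticed in the counts of detected genes within MCF-7 cells.

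The first pattern is the fall of tubulin mRNAs in 293T cells, where the list had a median log2 fold change of −0.93 (adjusted p = 0.258 with an estimated correlation) and differed from MCF-7 cells by −0.62 (adjusted p = 0.190 with an estimated correlation), so neither call holds there. If shared reads only moved counts between copies, the sum of the family would stay. The summed level of the 12 listed tubulins fell 1.97-fold, from 1704 ± 95.5 to 867 ± 45.2 CPM (mean ± SD, n = 3 per group). Since 9 of 11 members were already known to have fallen and 0 to have risen, the sum could hardly have come out otherwise. How shared reads were counted is not given in the sources used here, so a loss of such reads was not tested. A trend with GC content and gene length is excluded as the whole cause, since the median after its removal was −0.80 with 10 of 11 members below 0, and so is 2-ME replicate 1, since without it the median was −0.84. TUBG1, a gamma-tubulin outside the list, had −0.31 (SE 0.0595, edgeR adjusted p = 0.00169) and TUBG2 −0.22 (SE 0.0972, 0.0763). A biological response to a compound that binds tubulin stays open as a hypothesis, found and tested on the same data.

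The second pattern is that most mitosis genes were higher after 2-ME in 293T cells (23 rose and 4 fell, with TOP2A and CDK1 among the latter; adjusted p = 0.307 with an estimated correlation, so that call is lost there) and lower in MCF-7 cells, a median difference of 1.496. GC content and gene length are excluded as the whole cause, with medians after the trend's removal of 0.33 in 293T cells (0.35 before) and −1.20 in MCF-7 cells (−1.15 before). Library scaling moves all genes of like abundance together, and the list differed from abundance-matched genes by 0.22 in 293T cells (95% interval over resampled members 0.051 to 0.39) and by −1.16 in MCF-7 cells (−1.39 to −0.89). The matched genes had medians of 0.13 in 293T and 0.0095 in MCF-7 cells. These intervals treat members as independent and do not measure the spread between libraries. For the smaller difference in 293T cells they therefore do not decide. Without 2-ME replicate 1 the median in 293T cells was 0.32. A difference between the lines in how cells move through the cell cycle after 2-ME stays open as a hypothesis, and cell numbers or phases were not measured here.

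The third pattern is that MCF-7 cells had more genes detected after 2-ME (15482 to 15655) than in control (14755 to 14899), at 12435429 to 14932685 counts against 13812569 to 16742635. Fewer counts in a few abundant genes are excluded as the cause, since after thinning to 11600000 counts without the 10 most abundant genes the difference of the means was 782 genes, against 714 before. RNA of 293T cells would not be the main source at the median share of its abundant genes. After 2-ME, 51 genes abundant in 293T cells stood at a median of 0.0712% of their 293T level (0% to 0.737%). They were chosen for at most 3 counts over the MCF-7 controls, where their median was 0%. At 0.0712%, 21.02 of the 474 newly detected genes were expected (4.44%), and higher shares were not tested. Genomic DNA could not be decided, since olfactory receptor genes silent in control gained 27.6% of the reads per kilobase of other silent genes (1.89 against 6.85 after scaling to the library total) while all olfactory receptor genes gained 5.43 (6.38 to 11.8), nor could a first test of 293T RNA decide, in which 26.8% of newly detected genes had no count in 293T control (127 of 474, exact Clopper-Pearson 95% interval 22.9% to 31.02%). Expression of more genes after 2-ME stays open and was not tested.

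The lists differed as follows, in log2 fold changes in 293T minus MCF-7 cells, as medians for the lists: interferon-stimulated −0.94, tubulins −0.62, p53 targets −0.55, amino-acid and integrated stress response −0.45, cholesterol synthesis −0.30, NRF2 targets −0.29, immediate early 0.38, heat shock 0.41, mitochondrially encoded 0.81, SRF and YAP targets 0.93 and mitosis 1.496. The calls of tubulins (adjusted p = 0.190), immediate early genes (adjusted p = 0.0530) and mitochondrially encoded genes (adjusted p = 0.644) were lost with an estimated correlation.

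Genes with a response higher in 293T cells, in falling order of the difference in log2 fold change, began with EGR1 5.59, SPRY4 5.56, PADI1 4.68, NPPB 4.47, FOSL1 3.59, CPA4 3.33, TGFBI 3.19, CCN1 2.97 and ARC 2.46. Then followed HSPA8 2.29, RRM2 2.17, FOSL2 2.096, ETV5 2.06, MT2A 1.78, BUB1 1.76, ACTG1 1.73, CCNB1 1.66 and SPC24 1.57. After these came BAG3 1.42, ECT2 1.399, TOP2A 1.39, KRT18 1.37, CDK1 1.24, MT-ND5 1.23, FLNA 1.22, UBE2C 1.19 and MT-ND6 1.18. Next in order were ACTB 1.04, VCL 0.99, CCN2 0.94, MT-CO2 0.92, TIPARP 0.91, RFC3 0.87, CA12 0.87, H2BC5 0.75 and HK1 0.74. Smaller differences were those of SLC2A1 0.70, MT-ND1 0.65, CDC45 0.64, ENO2 0.63, DNAJC3 0.56, NDUFV1 0.46, UQCRC2 0.45, GREB1 0.43 and HSPB1 0.40. The smallest were those of RPL6 0.39, FN1 0.35, RPL7A 0.32, NDUFS2 0.32, KRT8 0.31, CYP1B1 0.28, GAPDH 0.24 and RPL3 0.22.

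Genes with a response lower in 293T cells, from the largest difference down, began with CXCL1 −5.67, IFIT2 −4.74, CYP1A1 −4.73, CEACAM1 −4.47, CHAC1 −3.86, ST8SIA5 −3.50, TSC22D3 −3.44, GJD3 −3.11 and IL16 −3.05. Then followed IFIT1 −2.39, DDIT4 −2.09, RPS17 −1.86, HMOX1 −1.84, TUBA1A −1.78, SLC7A11 −1.69, ZMAT3 −1.65, IDH1 −1.64 and TP53INP1 −1.61. After these came CXCL8 −1.46, WIPI1 −1.43, VLDLR −1.41, SNAI2 −1.399, IFIT3 −1.384, PCNA −1.32, H1-2 −1.32, CDH1 −1.29 and COL1A1 −1.15. Next in order were DNAJB9 −1.12, STUM −1.02, STC2 −0.98, HILPDA −0.97, CASP7 −0.78, INSIG1 −0.78, TUBB −0.69, TUBA1B −0.66 and SQSTM1 −0.65. Further down stood UCP2 −0.62, NR4A3 −0.56, LDLR −0.56, TXNRD1 −0.51, AEN −0.50, EDEM1 −0.47, H2BC12 −0.35 and HSPA5 −0.34.

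Of these differences, those of SPRY4, PADI1, NPPB, CPA4, TGFBI, CXCL1, IFIT2, CYP1A1, CEACAM1, ST8SIA5 and IL16 rest on a group that averaged below 3 counts per library in at least 1 line, so their sizes are uncertain.

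Genes with a group without counts differed with an edgeR adjusted p, given with no size, of 2.18e-06 for MMP10, 0.0370 for ATOH1, 5.81e-06 for COLEC12, 0.0258 for SLC6A19, 0.00234 for WT1, 0.000638 for OTOG, 0.000916 for CLEC4F, 0.00152 for PDE1B and 0.000273 for CCDC38. Several had few counts in the other group of that line, such as 3 over the 2-ME libraries for ATOH1 in MCF-7 and SLC6A19 in 293T cells.

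With 3 libraries against 3 there are 10 splits of the 6 libraries of a line, too few for a share under 0.05. The real split, the 1 with a result as large in each case, gave 7029 changed genes, 797 of them at least 2-fold, and 8 lists in 293T cells, where the highest of the other splits gave 0, 0 and 7. In MCF-7 cells it gave 7253, 941 and 18, and the highest of the others 0, 0 and 12. Every other split also called lists, at least 4 in 293T and 3 in MCF-7 cells, so a count of passing lists does not by itself exclude chance. For the genes whose response differs between the lines, the splits cannot tell either (100 splits, 6201, highest other 2150, 1 as large). Among the 83 splits that keep the real grouping of neither line the highest count was 0. The other splits that called genes keep the real grouping of 1 line and so hold that line's response. For genes changed the same way the splits cannot tell (2365, highest other 0, 1 as large), since other splits within a line call 0 genes and so leave nothing to share. For the lists whose response differs, chance is not excluded by the count over all 100 splits: the real split gave 11, the highest other 14, and 10 gave as many, the real one included. Of the 9 others, 8 keep the real grouping of 1 line and so hold that line's response; of 83 splits that keep it in neither line, 1 gave as many (11).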

How the results depend on the processing

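The settings were fixed before the data were examined, except those for the lists' difference between lines, which were chosen after seeing the data. With RLE size factors, no low-count filter, DESeq2, the replicate block and, for the counts of genes per line, 1 fit over all 12 libraries, each total stayed within 1.5 times: 6645 to 7531 genes changed in 293T cells (762 to 972 at least 2-fold), 6423 to 7475 in MCF-7 cells (901 to 1242), 2071 to 2375 changed the same way, and 6137 to 6270 with a differing response. Under these settings 8 lists passed in 293T cells, 17 or 18 in MCF-7 cells and 10 to 12 for the difference. RLE moved the median of all genes by 0.010 in 293T and 0.0034 in MCF-7 cells, and shared 6927 and 7227 calls with the results as reported. Leaving out 1 library gave 5641 to 8235 and 766 to 866 genes and 8 lists in 293T cells, 6635 to 6971 and 955 to 1065 genes and 17 to 18 lists in MCF-7 cells, 1944 to 2743 changed the same way, and 5528 to 6719 genes and 11 lists for the difference. By direction, the 173 genes at least 2-fold higher in 293T cells became 267 without a low-count filter, and the 624 lower became 705. The highest count in 293T cells, 8235, came without 2-ME replicate 1.

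Camera with an estimated correlation called 0 lists in 293T cells and 4 in MCF-7 cells, which is weaker, and 8 for the difference. It estimates the correlation within a list, which the preset value sets at 0.01. Calls were also lost where the estimate lay below 0.01. Examples were heat shock in 293T cells (estimate −0.038, camera adjusted p = 0.0753) and DNA replication in MCF-7 cells (−0.029, 0.0729). A call lost in this setting therefore does not by itself show that the genes of the list are correlated. Fry called 22 lists in 293T cells and 23 for the difference, which is stronger, and 25 in MCF-7 cells, and it asks another question. Signs that turned belong to values near 0 that did not pass. NR4A2 in 293T cells had −0.0055 without a low-count filter, −0.011 with the replicate block, and −0.18 to 0.14 without 1 library. NR4A1 in 293T cells ranged from −0.11 to 0.25 and COMT in 293T cells from −0.046 to 0.17 without 1 library, where COMT passed without 2-ME replicate 1 (adjusted p = 0.0267); the cause was not tested.

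Of the named genes' other calls, 11 weakened, 3 strengthened and 947 stayed without 1 library, and 3 weakened, 4 strengthened and 736 stayed under other settings. Of the lists' calls, 3 weakened and 345 stayed without 1 library, and 25 weakened, 21 strengthened and 302 stayed under other settings. The difference for SLC6A19 was lost without 293T 2-ME replicate 3. Deviations of replicates with the same number were correlated weakly (r of 0.055, 0.17 and −0.092 in 293T cells and 0.018, −0.0012 and 0.025 in MCF-7 cells, against −0.20 to 0.17 over the other pairs), too weakly to treat them as pairs, and of 209 genes and lists the block changed the call of 2, histones and NR4A2 in MCF-7 cells, and the sign of 1 without a call, NR4A2 in 293T cells. The pseudocount and the filter for normalized values were not run, since counts were tested. Depth limits genes near 3 counts per library, 0.149 to 0.241 CPM.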

Other observations

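Among the tests of this part, the pathway tests and the test of ERK pathway genes were chosen only after the result was seen. Pathways came from the annotation column of the authors' tables, which names KEGG pathways, and 223 with at least 15 tested genes were tested in 293T cells and 221 in MCF-7 cells. In 293T cells 17 passed camera. Genes of ribosome biogenesis rose in 47 of 72 cases and fell in 3 (camera adjusted p = 1.11e-06, median log2 fold change 0.37), genes of nucleocytoplasmic transport rose in 58 of 100 and fell in 8 (0.000103), and genes of the spliceosome rose in 54 of 127 and fell in 7 (0.00487). Genes of RNA polymerase rose in 19 of 33 and fell in 2 (0.0104). Genes of valine, leucine and isoleucine degradation fell in 22 of 43 cases and rose in 0 (0.0297), genes of fatty acid degradation fell in 17 of 37 and rose in 0 (0.0477), and genes of ECM-receptor interaction fell in 31 of 64 and rose in 12 (0.0337). With an estimated correlation 0 of these pathways passed (lowest adjusted p = 0.446), and in MCF-7 cells 0 of 221 passed.

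Several of the named genes that rose in 293T cells, SPRY4, ETV5, EGR1 and FOSL1, are known to be raised by the ERK branch of MAP kinase signalling. A hypothesis of higher ERK output in 293T cells after 2-ME predicts a rise of other genes known to follow ERK activity. These were tested without the named genes that raised it. They are not independent of those genes. DUSP4 and DUSP6 belong to the immediate early list, which had already been seen to rise, and ETV4 and SPRY2 are of the families of ETV5 and SPRY4. Of 8 such genes, 6 rose and 1 fell, with a median of 0.86 (camera adjusted p = 0.000779; adjusted p = 0.0894 with an estimated correlation). ETV4 had 3.44 (SE 0.149), EPHA2 1.29 (SE 0.0996), DUSP6 1.24 (SE 0.272), SPRY2 1.09 (SE 0.0801), DUSP4 0.63 (SE 0.134) and CCND1 0.39 (SE 0.0607), EPHA4 fell (−1.14, SE 0.0668), and PHLDA1 had −0.15 (SE 0.153). In MCF-7 cells 2 of 7 rose and 3 fell (camera adjusted p = 0.314). The result is what the hypothesis predicts for 293T cells by the preset correlation, it was found and tested on the same data, and phosphorylated ERK was not measured here.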
